A study of Mus musculus with 8 samples.

How the data were processed

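Murine embryonic fibroblasts (MEFs), connective tissue cells grown from mouse embryos, were studied with and without interferon-beta (IFN-beta), the antiviral cytokine that signals through the type I interferon receptor. Per the labels, the RNA-seq set held 2 untreated libraries and 2 libraries from cells given 100 units/mL of recombinant mouse IFN-beta for 6 h. The labels also list 4 chromatin samples, HA-tag immunoprecipitations of H3.3 and their inputs with and without IFN-beta, which were not analysed here. Groups were taken from the sample labels alone. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

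The values used were read counts per gene symbol, deposited by the authors as 1 table per library, not normalized and not pooled. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made with a TruSeq RNA kit. Per the submitters' processing notes, TopHat2 2.0.13 and HTSeq 0.7.2 were used with the mm9 mouse genome build. The gene annotation and the strand setting were not given in the sources used here. With an unknown strand setting, reads of overlapping genes on opposite strands cannot be separated, and reads that match several near-identical copies are left out of such counts. Levels of histone, H2, Gbp, Oas, Ifit, Slfn and similar multicopy genes are therefore uncertain.

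Each table held 24015 gene symbols and 5 summary lines that name no gene. The summary lines were left out of library sizes and tests. Of all records in the 4 tables, 39.3%, 41.4%, 42.7% and 38.7% were assigned to genes (untreated replicates 1 and 2, then IFN-beta replicates 1 and 2). Records outside any annotated gene made up 27.2%, 28.3%, 21.9% and 23.7% in that order. Records without a unique alignment made up 33.0%, 29.8%, 34.9% and 37.2%, and ambiguous ones between 0.466% and 0.535%.

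Genes were tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests on the deposited counts with TMM normalization, group as the only term and the default expression filter (minimum count 10, minimum total count 15). A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The standard error of a log2 fold change was approximated as its size divided by the square root of the F statistic. Counts scaled to a library of 1e6 counts (CPM) were computed from the counts with TMM-adjusted library sizes and are given as mean ± SD over the 2 libraries of a group. For genes with 0 counts in both untreated libraries, a lower bound of the fold was computed against a floor of 3 counts over the pooled untreated libraries, which corresponds to 0.0658 CPM. For genes with 1 to 3 pooled untreated counts, the ratio of depth-scaled counts is given with its 95% exact interval. Intervals and floors cover counting error only. With 2 libraries against 2, an exact permutation test could not go below p = 0.333, so no such test was used on single genes.

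In all, 33 gene lists with 518 symbols were fixed, 514 of the symbols were found in the tables, and the 29 lists with at least 3 tested members entered the list tests. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, then with an estimated correlation and with fry. With an estimated correlation, camera has only the residual degrees of freedom of the 4 libraries in 2 groups. It therefore has little power here. Fry asks whether the members of a list move on balance in a single direction, without comparing them with other genes. List p-values were adjusted over the 29 lists. For each list, members were also adjusted over the list alone.

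The genes named in the text follow a rule: the 12 largest rises and 8 largest falls among called genes with a mean CPM of 1 or more and no overlap between groups, up to 3 members of each list by p-value, 14 genes always reported, and the 5 called genes with the highest level in each direction. The rule, the lists, the test and the alternatives were set before the data were examined. Members outside the rule are named where a count of 5 or fewer needs them, and these, like Mir6236 and the genes in the closing part on neighbours, were chosen after their values were seen. Values of a few single genes that the rule names are not reported here.

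Alternatives were DESeq2 size factors in edgeR, total library size, upper quartile scaling, no count filter, a stricter filter (CPM of 1 in at least 2 libraries), the DESeq2 1.42.0 Wald test, limma-voom, a replicate block, another prior count (0.5) and each library left out. With a library left out, 1 group holds a single library and the spread comes from the other group alone. Adjusted p-values and calls of those fits are therefore uncertain. Added after the data were seen was a fit without Rn45s, Lars2 and Mir6236. The edgeR procedure was tested on simulated data with the means of the untreated libraries and the library sizes of this comparison (11883 genes). Changed genes, 50 per fold size, were drawn from genes with a mean count of at least 50, with as many raised as lowered. Recovered were 34% of genes changed 1.5-fold, 86% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, and 10 of 169 calls were false. Recovery among genes with fewer counts, or with mostly rises as in these data, was not simulated. With no simulated change, 0 genes were called. Simulated genes varied independently of each other, so these counts of false calls leave out library differences that many genes share.

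Gene order along chromosomes was taken from a RefSeq table of the GRCm38.p6 assembly, which matched 99.5% of the tested genes. That assembly differs from mm9, so no coordinates or gene lengths are given and gene length was not examined. Further values were computed with Python 3.11.15 and SciPy 1.17.1, and plots with matplotlib 3.10.9.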

Results

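RNA from MEFs of embryonic day 12.5 embryos on a C57BL/6 background, at passages 15 to 18, was sequenced without treatment and after 6 h with 100 units/mL of IFN-beta. The series presents a mouse model with HA-tagged histone H3.3, the variant that is deposited outside DNA replication, and asks in part how H3.3 and transcripts behave during an interferon response. Only the RNA-seq libraries were analysed here. The untreated libraries held 18528685 and 24817342 gene counts, and the IFN-beta libraries 18901845 and 20714161. Counts of replicates differed by more than sampling noise, with a chi-square per gene of 34.2 for the untreated pair and 11.98 for the IFN-beta pair, against 103 to 162 between groups. The first principal component, with 84.2% of the variance, separated the groups.

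IFN-beta raised a large antiviral programme. Of 12128 tested genes, 574 were higher and 60 were lower after treatment (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), and 434 of the higher genes and 12 of the lower ones changed at least 2-fold. The lower counts depend on the processing, with 350 lower genes under total library size scaling, 381 without a count filter and 1728 without untreated replicate 2 (35, 43 and 130 of them at least 2-fold). The higher count moved too, to 478 with total library size scaling and 863 without a count filter. Total library size scaling moved the median log2 fold change of all tested genes from -0.02 to -0.16. Under that scaling the larger share of Rn45s and Lars2 after IFN-beta lowers the values of all other genes. Many of the strongest risers were close to silent without the cytokine: 50 of the higher genes had 3 or fewer pooled untreated counts, and 11 of these had 0. Mx1 had 0 untreated counts and 3088 and 4972 counts after IFN-beta, which was at least 3220-fold higher. Tgtp2, an immunity-related GTPase, was at least 1156-fold higher, and Oas2, which makes the 2-prime-5-prime oligoadenylates that activate RNase L, at least 222.9-fold higher. Rsad2 (viperin) had 2 pooled untreated counts and a ratio of 13430 (95% interval 3717 to 110900). The ratio was 6066 for I830012O16Rik (2075 to 29420), 5146 for Ifi44 (1424 to 42500), 3553 for Mx2 (983 to 29340), 3462 for Ddx60 (620.9 to 136800), 3051 for Gm4951 (547.1 to 120600) and 2137 for Gbp4 (383.1 to 84460). Iigp1, another immunity-related GTPase, rose from 0.135 ± 0.0298 to 629 ± 6.37 CPM (SD, n = 2), and the chemokine gene Cxcl10 from 1.10 ± 0.00576 to 1970 ± 192 CPM.

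**Figure D1:**
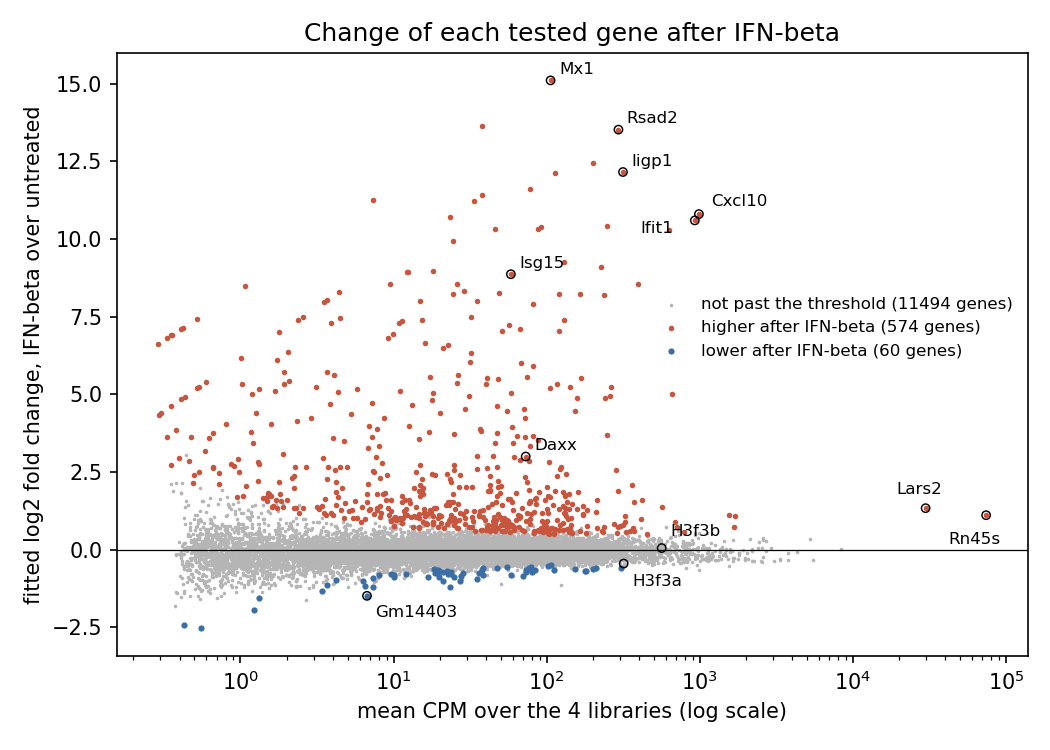
Fitted log2 fold change after IFN-beta (y axis) against the mean CPM over the 4 libraries on a log scale (x axis), with 1 point per tested gene; red and blue points are the 574 higher and 60 lower genes, and circled genes are named. Rises reach far greater sizes than falls; for the 50 genes with 3 or fewer untreated counts, Mx1 and Rsad2 among them, the fitted value depends on the prior count.

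Several genes of the interferon signalling chain rose. In the list of receptor and JAK-STAT genes, 5 of 9 tested members rose. Stat2 went from 3.44 ± 0.386 to 114 ± 22.2 CPM (log2 fold change 5.04 ± 0.20 SE, adjusted p = 7.6e-08) and Irf9 from 6.51 ± 1.16 to 88.5 ± 2.98 CPM. The proteins of these genes act together in carrying the signal to DNA. Jak2 and Stat3 rose by a log2 fold change of 0.62 each. The receptor genes Ifnar1 (-0.14 ± 0.13, adjusted p = 0.596) and Ifnar2 (0.22 ± 0.15, adjusted p = 0.460) did not pass the test. The list as a whole was higher (camera adjusted p = 6.6e-07, but adjusted p = 0.157 with an estimated correlation). Among the negative regulators, 3 of 10 rose, and 4 when adjusted over the list alone. These were Usp18, the ISG15-removing protease that also restrains receptor signalling (0.374 ± 0.207 to 496 ± 2.82 CPM), and the feedback inhibitors Socs1 (log2 fold change 1.83) and Socs2 (1.64). That list had an adjusted p of 0.0010, and an adjusted p of 0.164 with an estimated correlation.

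**Figure D2:**
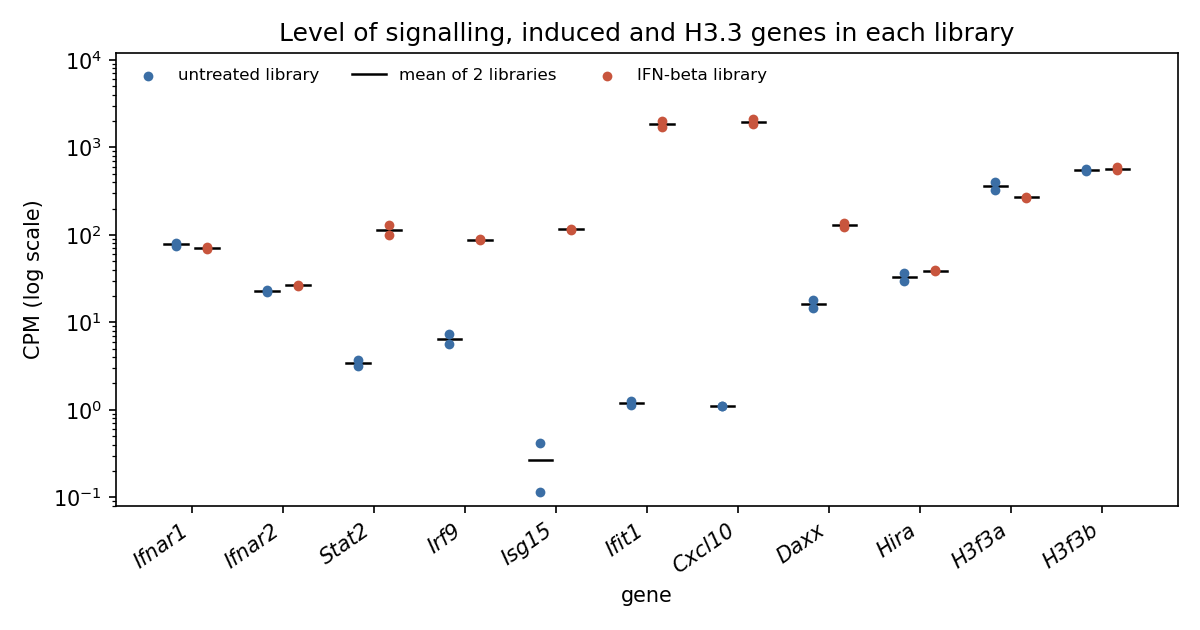
CPM on a log scale (y axis) of 11 genes (x axis) in each of the 2 untreated (blue) and 2 IFN-beta (red) libraries, with black bars at the mean of each group. The receptor genes, Hira, H3f3a and H3f3b lie close together in the 2 groups, while Stat2, Irf9, Isg15, Ifit1, Cxcl10 and Daxx lie apart.

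Genes of the interferon-induced transcription factor list rose in 11 of 13 tested cases, with a median log2 fold change of 3.57 (3.43 with genes near 0 untreated counts at their bound). Irf7, the factor that drives interferon-alpha genes, had 3 pooled untreated counts and a ratio of 1401 (479 to 6797). The nuclear body gene Sp100 (log2 fold change 6.65) and Ifi35 (3.95) also rose, and Irf3 (-0.04) and Tcf7l2 (-0.25) did not pass. Of 31 tested antiviral effectors, 29 rose, with a median of 5.71. Ifit1, which binds viral RNA ends, went from 1.19 ± 0.0777 to 1850 ± 179 CPM, and Ifit3 from 1.02 ± 0.101 to 1262 ± 72.1 CPM. Ifitm2 (0.16) and Ifi27 (0.48) did not pass. All 12 tested genes of the ISG15 and ubiquitin ligase list rose, with a median of 4.92. Isg15, the ubiquitin-like modifier, went from 0.265 ± 0.214 to 116 ± 2.28 CPM, Dtx3l from 5.53 ± 0.480 to 204 ± 21.4 CPM, and the antibody receptor gene Trim21 had a log2 fold change of 5.53. All 17 tested guanylate-binding protein and immunity-related GTPase genes rose, with a median of 8.27 (8.23 with genes at their bound), including Gbp7 (8.19) and Irgm1 (5.25). Adjusted over the list alone, the counts for these 4 lists were 11, 29, 12 and 17, as over all genes.

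Sensors of viral nucleic acid rose in 14 of 18 cases, and in 16 when adjusted over the list alone, with a median of 3.63. Ifih1 (MDA5) went from 1.81 ± 0.153 to 239 ± 14.1 CPM, Ddx58 (RIG-I) from 10.5 ± 1.24 to 307 ± 9.53 CPM and the endosomal receptor gene Tlr3 from 2.62 ± 0.115 to 159 ± 29.4 CPM. The sensors' signalling partners Tmem173 (STING, 0.55), Mavs (0.21) and Ticam1 (-0.01) did not pass, nor did Aim2 (1.49). In the PARP family 7 of 9 tested genes rose, over the list alone as well, with a median of 3.02. These included Parp14 (8.23), Parp9 (5.54) and Parp12 (4.46), which add mono-ADP-ribose or, for Parp9, work with Dtx3l, while the DNA repair genes Parp1 (0.17) and Parp2 (-0.12) did not pass. In the Schlafen family 6 of 7 rose, and 7 over the list alone, led by Slfn8 (6.02), Slfn2 (5.11) and Slfn9 (4.23), and Slfn5 (0.48) was the member that did not pass over all genes.

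MHC class I presentation genes rose in 19 of 22 tested cases, also adjusted over the list alone, with a median of 2.06. The peptide transporter gene Tap1 went from 0.764 ± 0.169 to 113 ± 3.21 CPM, the immunoproteasome gene Psmb8 from 0.475 ± 0.136 to 41.8 ± 0.194 CPM, and Psmb10 had a log2 fold change of 3.02. The chaperone genes Canx (0.09), Calr (0.22) and Pdia3 (0.08) did not pass. Of the MHC class II list only Ctss had enough counts to be tested (0.65 ± 0.56, adjusted p = 0.586). Chemokine and cytokine genes rose in 10 of 16 tested cases, over the list alone as well, with a median of 1.55. Besides Cxcl10, Il6 went from 1.01 ± 0.255 to 25.5 ± 1.53 CPM and the death ligand gene Tnfsf10 (TRAIL) from 0.828 ± 0.152 to 12.96 ± 0.374 CPM. All 6 tested genes of a list often linked to interferon-gamma rose, over the list alone as well, with a median of 6.74, or 5.01 with genes at their bound. They included Cd274 (PD-L1, 0.774 ± 0.139 to 63.6 ± 9.55 CPM), Gbp2 (8.54) and Gbp6 (0.298 ± 0.314 to 69.6 ± 8.46 CPM), but 5 of the list's genes also stand in other lists.

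With the preset correlation, camera gave adjusted p-values of 1.3e-50 for antiviral effectors, 3.5e-38 for guanylate-binding proteins and immunity-related GTPases, 2.5e-26 for MHC class I presentation, 1.6e-25 for sensors, 4.1e-24 for ISG15 and ubiquitin ligases and 2.8e-16 for induced transcription factors. They were 1.6e-12 for Schlafen genes, 2.5e-12 for the interferon-gamma list, 2.1e-11 for PARP genes and 2.9e-10 for chemokines and cytokines. Each of these 10 lists had the same adjusted p = 0.0765 with an estimated correlation, so these calls do not hold there. The estimate itself was below 0 for induced transcription factors (-0.079), sensors (-0.052), chemokines and cytokines (-0.058) and the interferon-gamma list (-0.154). That test has few degrees of freedom with these libraries, so missing the threshold there does not decide whether a list changed. Fry, which does not compare a list with other genes, gave adjusted p-values from 0.00015 to 0.0023 for them.

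Cell death genes changed in part. Of 17 tested members 7 rose, and 8 when adjusted over the list alone, among them the necroptosis executor Mlkl (log2 fold change 2.18), the inflammatory caspase gene Casp4 (1.79) and Xaf1, an antagonist of a caspase inhibitor (4.52). The median was 0.31 and the list's adjusted p was 0.00018 (adjusted p = 0.340 with an estimated correlation). No NF-kB target passed the test among 14 over all genes or over the list alone, with Tnfaip2 at 0.58 ± 0.19 (adjusted p = 0.140), Nfkbiz at 0.24 and Relb at -0.29, and the list was not called (camera adjusted p = 0.439). With all libraries kept, Tnfaip2 passed only without a count filter (adjusted p = 0.0093) and with the replicate block (0.0437). Its log2 value was 0.92 without untreated replicate 2. Of 19 immediate early genes 2 rose, and 4 over the list alone. These were the transcription factor genes Klf4 (11.6 ± 0.617 to 34.0 ± 11.0 CPM, log2 fold change 1.55 ± 0.22) and Myc (0.80 ± 0.16, adjusted p = 0.0185), while Jun was at 0.61 (adjusted p = 0.0638, from 1.6e-08 to 0.303 over the alternatives, 5 of which it passed). The Myc call was lost with total library size scaling (adjusted p = 0.0558) and without IFN-beta replicate 1 (0.0828), over a range from 5.2e-11 to 0.0828 across alternatives. The list's adjusted p was 0.0040, with adjusted p = 0.633 with an estimated correlation, 0.507 without IFN-beta replicate 1 and 0.0567 without untreated replicate 2.

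Transcripts of the histone variant that the mouse model tags showed no called change, whereas the chaperone gene Daxx rose. Daxx, which with Atrx loads H3.3 at repeats and telomeres, went from 16.1 ± 2.32 to 129.6 ± 7.53 CPM (log2 fold change 3.001 ± 0.15, adjusted p = 5.1e-07, higher in both treated libraries than in both untreated ones). H3f3a was at 366 ± 55.1 CPM untreated and 269 ± 6.96 CPM treated (-0.44 ± 0.14, adjusted p = 0.117), and H3f3b at 552 ± 19.6 and 573 ± 28.8 CPM (0.05 ± 0.12, adjusted p = 0.862). Hira, which loads H3.3 at active genes, was at 33.2 ± 4.85 and 39.1 ± 1.18 CPM (0.24 ± 0.15, adjusted p = 0.446), and Nasp at -0.37. Daxx was the 1 call among 12 tested H3.3 genes and chaperones, over the list alone as well. The list was not called (camera adjusted p = 0.868, but fry adjusted p = 0.0198). Its members were split, with 6 of 12 below 0 and a median of 0.01. With all libraries kept, H3f3a passed only with total library size scaling (adjusted p = 0.0337) and without a count filter (0.0293). Without untreated replicate 2 the log2 value of H3f3a was -0.59 and that of Hira 0.40. The value of H3f3b turned to -0.09 with total library size and to -0.02 with upper quartile scaling.

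Chromatin factors linked to H3.3, among them Supt6 (0.45), Whsc1l1 (0.33) and Kdm2a (0.22), gave 0 calls among 11 tested genes, over the list alone as well (camera adjusted p = 0.180). Of 30 replication-dependent histone genes none passed here over all genes or over the list alone, and the median was -0.26. Hist2h2bb was at -0.58 ± 0.18 (adjusted p = 0.119), Hist1h2ae at -0.55 and Hist1h2bg at -0.48. As a list they were lower (camera adjusted p = 0.00056), but adjusted p = 0.790 with an estimated correlation, 0.481 without IFN-beta replicate 1 and 0.101 without untreated replicate 1. Other settings called members lower. Hist1h2bg passed with total library size (adjusted p = 0.0378) and without a count filter (0.0195), Hist1h2ae without a count filter (0.0337) and Hist2h2bb with both (0.0499 and 0.00097), by DESeq2 (0.0408) and without IFN-beta replicate 2 (0.0325), and all 3 passed without untreated replicate 2. Their adjusted p-values ran up to 0.887, 0.999 and 0.969 over the alternatives.

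Most other programmes of the fibroblasts gave few calls or none. Of 28 cell cycle genes only the replication helicase gene Mcm6 rose (0.54 ± 0.13, adjusted p = 0.0498), 0 passed when adjusted over the list alone, and Bub1 (-0.51) and Ccne2 (-0.44) did not pass (list camera adjusted p = 0.810, fry adjusted p = 0.0104). With all libraries kept, Bub1 passed as lower only with total library size (adjusted p = 0.0459) and without a count filter (0.0092). Its log2 value was -0.72 without untreated replicate 2. Ccne2 passed as lower only with total library size (0.0464), and its value was -0.39 without untreated replicate 1 and -0.46 without untreated replicate 2. The Mcm6 call was lost under 8 alternatives, with adjusted p-values up to 0.388. Of 13 p53 targets Eda2r rose (1.02 ± 0.19, adjusted p = 0.0103, but 0.105 without IFN-beta replicate 2), and Aen (0.44) and Ccng1 (-0.43) did not pass (list adjusted p = 0.699, but fry adjusted p = 0.0074). Of 15 unfolded protein and amino acid stress genes Sesn3, a sestrin that restrains growth signalling, rose (0.86 ± 0.20, adjusted p = 0.0304), while Chac1 (0.38) and Ppp1r15a (0.32) did not pass (list adjusted p = 0.288). Without untreated replicate 1 that list was called higher (adjusted p = 0.0055), and Chac1 (0.0043) and Ppp1r15a (0.0059) passed. The Sesn3 call was lost with total library size scaling (adjusted p = 0.0698) and without either IFN-beta replicate (0.0836 and 0.0943). The p53 and stress lists had 1 call each over the list alone too. Of 32 matrix and fibroblast genes 2 rose, and 5 over the list alone. These were the matrix glycoprotein genes Thbs1 (1087 ± 500 to 2300 ± 322 CPM, adjusted p = 0.0477) and Tnc (972 ± 457 to 2110 ± 56.0 CPM, adjusted p = 0.0368), and Timp1 was at 0.71 (adjusted p = 0.0529). Timp1 passed in 8 alternatives, among them DESeq2 (adjusted p = 0.0030) and limma-voom (0.0431), over a range from 2.4e-12 to 0.105. The calls of Thbs1 and Tnc were lost with DESeq2 (adjusted p = 0.216 and 0.173) and with total library size or upper quartile scaling (0.0507 to 0.0827). The matrix list had an adjusted p of 0.0070, an adjusted p = 0.465 with an estimated correlation and 0.0802 without IFN-beta replicate 1.

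There were 0 calls among 20 cholesterol synthesis genes (Sc5d 0.32, Msmo1 -0.30, Idi1 -0.28, list adjusted p = 0.810), 23 oxidative phosphorylation genes (Ndufb3 -0.56, Cox7c -0.44, Ndufa2 -0.40, list adjusted p = 0.137), 13 housekeeping genes (Ppia -0.39, Tfrc -0.37, list adjusted p = 0.979) and 6 nuclear long noncoding RNAs (Kcnq1ot1 -0.44, Gas5 -0.34, Neat1 0.28, list adjusted p = 0.302). These counts were also 0 when adjusted over the list alone. Without untreated replicate 2 the oxidative phosphorylation list was called lower (adjusted p = 0.0041). With all libraries kept, Ndufb3 passed as lower only with total library size (adjusted p = 0.0419) and without a count filter (0.0173). Its log2 value was -0.75 without untreated replicate 2. For housekeeping genes the median (-0.03) and the mean (0.01) differ in sign. Over all tested genes, 2202 had an unadjusted p under 0.05.

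**Figure D3:**
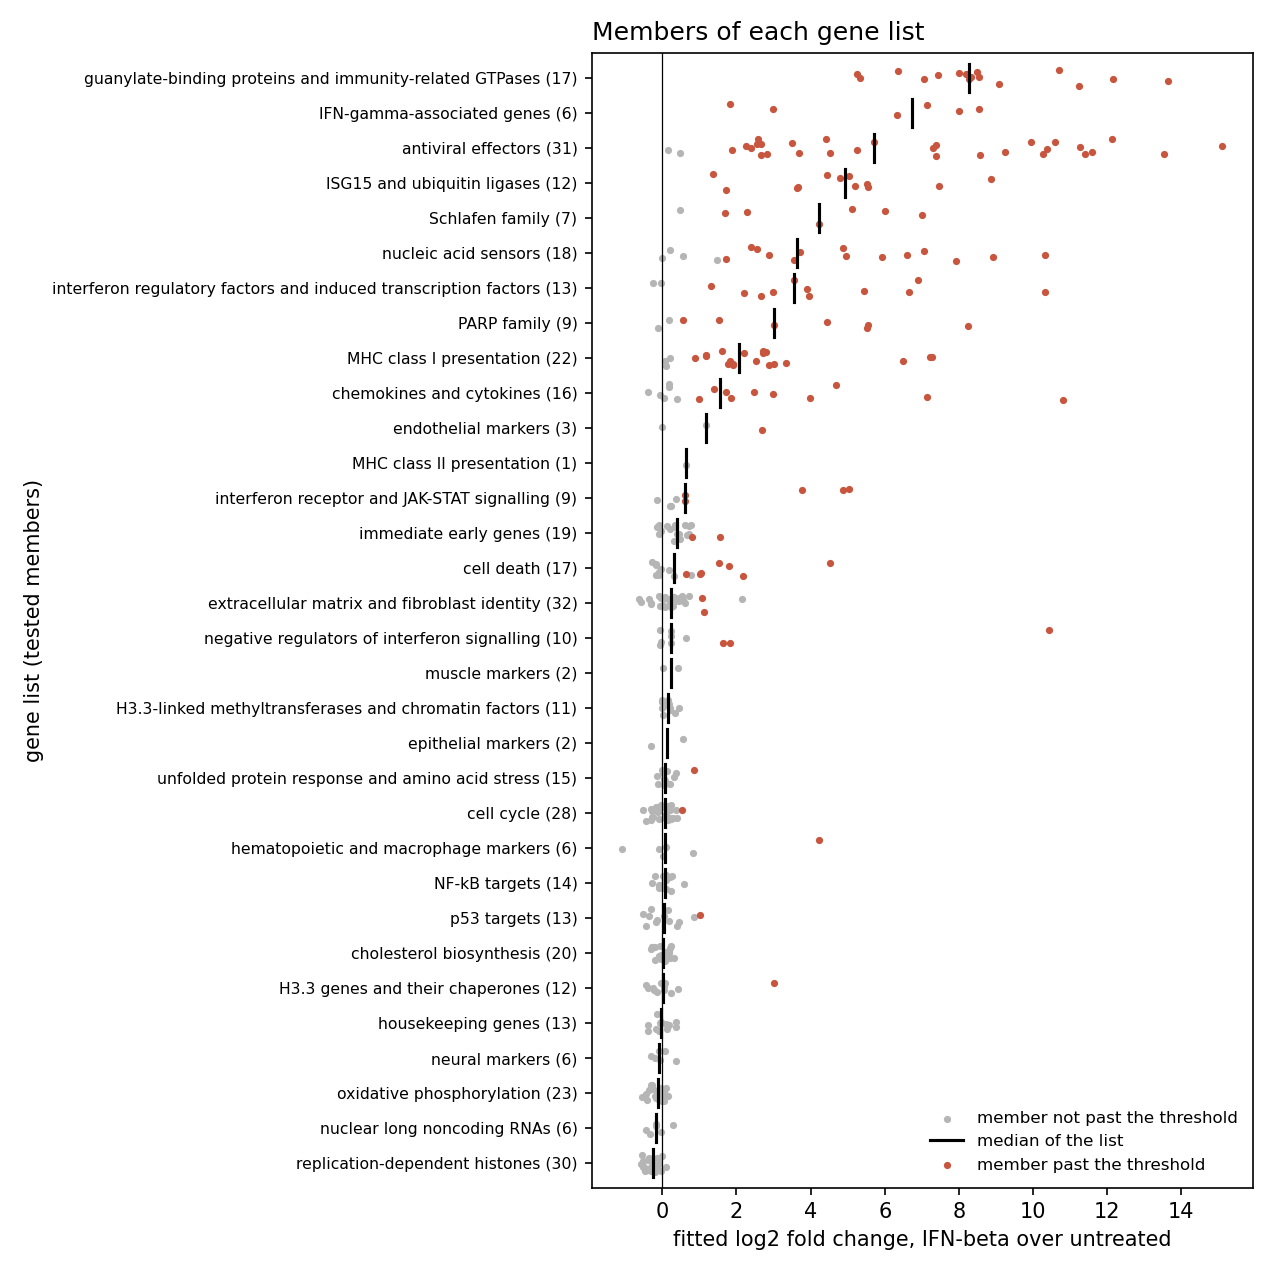
Fitted log2 fold change after IFN-beta (x axis) of each tested member of the gene lists (y axis, with the number of tested members), with red points past the threshold, grey points not past it and black bars at the medians. Members of the interferon lists spread to the right of 0, with a median of 8.27 for the guanylate-binding proteins and immunity-related GTPases, while most other lists centre near 0.

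Markers of other cell types were mostly too low to test and did not move together. Among 6 tested blood and macrophage markers Mpeg1, which encodes a pore-forming protein of phagocytes, rose from 0.922 ± 0.607 to 16.5 ± 1.84 CPM (4.23 ± 0.34, adjusted p = 2.2e-05), while Lyz2 was at -1.08 (adjusted p = 0.349) and Cd68 at 0.82 (adjusted p = 0.274). With all libraries kept, Lyz2 passed only without a count filter (adjusted p = 0.00088) and with the replicate block (0.0079). Its untreated libraries were at 8.52 and 2.54 CPM and its treated ones at 3.81 and 1.36 CPM. The log2 value of Lyz2 was -1.74 without untreated replicate 2 and 0.0269 without untreated replicate 1. The list was not called (camera adjusted p = 0.224), except without IFN-beta replicate 2 (0.0115). Of 3 tested endothelial markers Cdh5 rose from 0.166 ± 0.0874 to 1.15 ± 0.274 CPM (adjusted p = 0.0140, but 0.0777 without IFN-beta replicate 1). Kdr was at 1.18 (adjusted p = 0.177) and Egfl7 at -0.02. This list had an adjusted p of 0.0395, an adjusted p = 0.581 with an estimated correlation, and was not called without a count filter (0.705), without IFN-beta replicate 1 (0.0802) or without either untreated replicate (0.101 and 0.0896). Over the list alone the counts were 1 for blood and 2 for endothelial markers. Neither the 6 neural markers (Tubb3 -0.32, Gap43 0.37, Elavl4 -0.20, list adjusted p = 0.745), nor 2 epithelial (Krt19 -0.31, Krt7 0.57) and 2 muscle markers (Tnnt2 0.43, Acta1 0.03) gave a call over all genes or over the list alone, and 0 erythroid markers could be tested.

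The highest-level genes among the called rises were Rn45s, the ribosomal RNA precursor (46788 ± 9006 to 101090 ± 9265 CPM, log2 fold change 1.11, adjusted p = 0.0189), and Lars2 (16876 ± 542 to 42663 ± 3075 CPM, 1.34, adjusted p = 0.0016), followed by Thbs1, the interleukin-33 receptor gene Il1rl1 (1241 ± 88.4 to 2076 ± 199 CPM, adjusted p = 0.0130) and Tnc. Without IFN-beta replicate 1 the calls of Rn45s (adjusted p = 0.208) and Il1rl1 (0.230) were lost. Together Rn45s and Lars2 took 6.70 ± 1.11% of gene counts without and 13.7 ± 1.03% with IFN-beta.

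Lower genes changed little by comparison, with a median log2 fold change of -0.77 among the 60. Among lower genes with a mean CPM of at least 1 and no overlap between groups, the largest falls were in Fam13c (-1.94 ± 0.44, from 1.97 ± 0.591 to 0.496 ± 0.225 CPM), the prostaglandin F receptor gene Ptgfr (-1.55), Gm14403 (-1.48 ± 0.21, from 9.88 ± 1.16 to 3.52 ± 0.298 CPM, adjusted p = 0.0018), Sec16b (-1.33), the zinc finger gene Zfp799 (-1.21, adjusted p = 0.0048), Tmem119 (-1.19), Macc1 (-1.16) and the vessel-remodelling ligand gene Angpt2 (-1.12). The lower genes with the highest levels were Slc5a3, a myo-inositol transporter gene (363 ± 26.7 to 243 ± 9.70 CPM), Depdc1a (-0.60), Klhl9 (-0.60), the hyaluronan receptor gene Hmmr (-0.69) and the caveolin gene Cav2 (-0.69). Of these 13 genes only Gm14403 and Zfp799 held their call in every alternative run. Ptgfr, Fam13c, Tmem119 and Klhl9 lost theirs under another tool or scaling (adjusted p = 0.134 and 0.0533 by DESeq2, 0.0750 by limma-voom and 0.0533 with DESeq2 size factors), and without IFN-beta replicate 1 the call was lost by all 13 except Gm14403, Zfp799 and Tmem119 (0.0578 to 0.387).

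The split between higher and lower genes depended on scaling: 478 higher and 350 lower with total library size, which moved the median of all genes from -0.02 to -0.16, and 520 and 128 with upper quartile scaling, against 574 and 60 here. Total library size scaling sets other genes lower where Rn45s and Lars2 take a larger share, which was 6.70% without and 13.7% with IFN-beta. How much of the shift this made was not tested. Leaving out untreated replicate 2 gave 1885 higher and 1728 lower genes, and leaving out IFN-beta replicate 1 gave 470 and 24. Of the 60 lower calls, 9 held without IFN-beta replicate 1 and 24 without IFN-beta replicate 2. Among the named genes that did not pass, 35 passed in at least 1 alternative. Without untreated replicate 2 alone these were Acta1, Aen, Cox7c, Gas5, Hira, Idi1, Kdm2a, Msmo1, Nasp, Ndufa2, Neat1, Ppia, Supt6, Tnnt2 and Whsc1l1, and without untreated replicate 1 alone Chac1, Ctss, Krt19, Ppp1r15a and Sc5d. Ccng1 and Tfrc passed with total library size scaling and without untreated replicate 2, and Kcnq1ot1 without a count filter and without untreated replicate 1. Groups did not overlap in 50.7% of tested genes, against 33.3% expected by chance. Genes of a library vary together, so differences between libraries unrelated to treatment could also exceed that share.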

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

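All tests in this part were chosen after the results were seen.

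The share of records without a unique alignment, which enters no gene count, was 31.4 ± 2.24% in the untreated and 36.03 ± 1.59% in the IFN-beta libraries (SD, n = 2), and both treated libraries lay above both untreated ones. It was singled out as a signal outside the gene counts that exceeds its level in the control libraries.

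Rn45s, Lars2 and Mir6236 were all higher after IFN-beta, with log2 fold changes of 1.11, 1.34 and 1.38. If each count came from ribosomal RNA reads that vary in amount between libraries, the counts of Lars2 and Mir6236 would keep their ratio to Rn45s. Between replicates of a group the log2 ratios differed by up to 0.423, as much as Rn45s itself did (0.395 in the untreated pair, where Lars2 moved by 0.0655 and Mir6236 by -0.011). In the IFN-beta pair Lars2 followed Rn45s (-0.147 and -0.187), but Mir6236 moved by 0.236. The replicates therefore do not show that the 3 move together. A first comparison over all 4 libraries (ratios within 0.667) was set aside, since the genes were picked for similar rises. Ribosomal RNA kept in differing amounts by each preparation and an effect of IFN-beta on ribosomal RNA both stay open, because treatment and preparation cannot be separated with 2 libraries a group.

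Some gene families leaned lower after IFN-beta, with 0 members called higher or lower in any of them. The median log2 fold change was -0.23 for 94 ribosomal protein genes, -0.28 for 55 histone genes, -0.26 for 44 Nduf genes of respiratory complex I and -0.22 for 50 small nucleolar RNAs. Relative to other genes the differences ran from -0.21 to -0.27. Low counts are argued against by the members of at least 10 CPM, whose medians (-0.23, -0.29, -0.26 and -0.26) had 95% bootstrap intervals over members that ended at -0.14 or lower in all 4 families. These intervals treat members as independent and hold no spread between libraries, so they are too narrow. Among replication-dependent histones the estimated correlation between members was 0.91. In 3 of the 4 families the untreated replicates differed from each other, relative to other genes, by at least as much as treatment did (for histones 0.25 against 0.27, while their treated replicates differed by 0.39), so library differences unrelated to treatment could account for the lean, and a response to IFN-beta was not excluded.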

How the results depend on the processing

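All alternatives below were planned except the fit without Rn45s, Lars2 and Mir6236, which was chosen after seeing the data and gave 586 higher and 54 lower genes, with 569 and 53 of the original calls (3 of the other higher calls are these genes themselves). The count of higher genes ranged from 478 to 692 over other scalings, filters, tools and the replicate block, apart from 863 without a count filter, and from 470 to 1885 with a library left out. Lower genes were less stable: 350 with total library size, 128 with upper quartile scaling, 381 without a count filter, 103 by the DESeq2 Wald test, and 24 to 1728 with a library left out. Genes at least 2-fold higher ranged from 371 to 581, while those at least 2-fold lower numbered 35 with total library size, 20 with upper quartile scaling, 43 without a filter and 12 to 130 with a library left out. Among H3.3 genes and chaperones 2 passed with total library size and 2 without a filter, and 1 to 6 with a library left out, the highest without untreated replicate 2. Without untreated replicate 1 there were 861 higher, 227 lower and 22 at least 2-fold lower genes, and without IFN-beta replicate 2 there were 527, 55 and 24. Of the original 574 higher and 60 lower calls, 574 and 59 held without untreated replicate 1, 572 and 59 without untreated replicate 2, 444 and 9 without IFN-beta replicate 1, and 472 and 24 without IFN-beta replicate 2. The fits that leave 1 library in a group assume that it varies like the other group, and the cause of these shifts was not tested.

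The labels do not say whether equal replicate numbers mark a shared day, and with 2 libraries a group the deviations give a single correlation (-0.0334), so pairing was neither shown nor excluded. With the replicate block 692 genes were higher, 155 lower and 38 at least 2-fold lower.

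Of 29 tested lists 17 passed, 0 with an estimated correlation, 16 with fry and 13 to 18 with a library left out. Fry alone called, as higher, H3.3 genes and chaperones (adjusted p = 0.0198), cell cycle (0.0104) and p53 targets (0.0074). Their members were split, with 6 of 12, 13 of 28 and 6 of 13 below 0 and medians of 0.01, 0.07 and 0.06. Called by camera but not by fry were immediate early genes (fry adjusted p = 0.461), replication-dependent histones (0.533), matrix and fibroblast genes (0.176) and endothelial markers (0.198). Of 121 named genes 74 passed, 20 of these lost the call in at least 1 alternative, none of the 74 changed sign, and 35 others passed in at least 1 alternative. Uncalled values that turned were those of Acta1 (-0.115 with total library size, -0.0336 with upper quartile scaling) and H3f3b (-0.0893 and -0.0186). With a library left out, log2 values ran from -0.49 to 1.07 for Acta1, -0.10 to 1.74 for Ctss, -0.22 to 0.17 for Egfl7, -0.42 to 0.0123 for Elavl4, -0.54 to 1.17 for Krt7, -1.99 to 0.0269 for Lyz2, -0.54 to 0.0021 for Msmo1, -0.0847 to 0.61 for Neat1, -0.0253 to 0.62 for Ppp1r15a and -0.49 to 0.0025 for Relb. At this depth 34% of 1.5-fold changes were recovered in simulated data, among genes with a mean count of at least 50. Small changes can therefore be missed.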

Other observations

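All tests in this part were chosen after the result was seen. Many of the strongest risers sat next to each other on the chromosomes. Of 238 genes at least 4-fold higher, 100 stood in 28 runs of adjacent tested genes. The longest run, 9 genes on chromosome 1, held Pyhin1, Pydc3, Pydc4, Ifi203, Ifi204, Ifi205, Mnda and Mndal of the PYHIN family, which includes DNA sensors. A run of 8 on chromosome 11 held the immunity-related GTPase genes Irgm1, Tgtp2 and Ifi47, and runs of 6 held the Ifit genes on chromosome 19 and the Oas genes on chromosome 5. Other runs held Gbp genes on chromosomes 3 and 5, Slfn genes on 11, Trim30a and its relatives on 7, Apol genes on 15 and Phf11 genes on 14. Psmb9, Tap1, Psmb8 and Tap2 stood together on 17. Daxx stood next to BC051226 (log2 fold change 2.36, adjusted p = 0.0015 by edgeR), which also rose. Whether reads ran on from a gene into its neighbour was not examined for this pair or for the runs named here.

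There were 72 adjacent pairs, against a mean of 4.67 and a highest of 14 in 10000 shuffled gene orders. Whether tandem copies of a gene family are the whole source was not decided, because each way of leaving copies out has a fault. Without pairs of a family and pairs with provisional symbols 12 pairs remained (shuffled mean 3.82, a share of 0.0002 as high), but some stand between interleaved copies. Without whole runs that hold at least 2 genes of a family 5 remained (mean 3.81, share 0.338), which also drops unrelated neighbours. That step lowered the observed count from 12 to 5 but the shuffled mean only from 3.82 to 3.81. Observed and shuffled orders are therefore not treated alike there, and the share of 0.338 decides nothing. Both counts were set after a first one by symbol stem (36, shuffled mean 4.63) had been seen, and the 5 pairs are Rsad2 with Cmpk2, Rbm43 with Nmi, Serping1 with Ube2l6, Ppm1k with Herc6 and Islr with Pml. Reads running on from an induced gene into its neighbour stay open, since the smaller CPM gain of these pairs had a median of 28.3% of the larger, 2 pairs were under 10%, and strand was not known.

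Zinc finger genes with Zfp symbols made up 7 of the 60 lower genes, 11.7% against 2.61% of tested genes, a group picked after the lower genes were seen. They were Zfp40, Zfp60, Zfp788, Zfp799, Zfp808, Zfp934 and Zfp938, while 6 other Zfp genes were higher. Of 316 tested Zfp genes 225 had a value below 0, with a median of -0.19, against -0.02 for all tested genes. Of the 60 lower calls, 9 held without IFN-beta replicate 1 and 24 without IFN-beta replicate 2.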
